A study of Bubalus bubalis with 9 samples.

How the data were processed

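RNA of granulosa cells from ovarian follicles of Chinese buffalo (Bubalus bubalis) was extracted with Trizol, and libraries were made from 3 µg of RNA per sample by standard Illumina protocols, per the labels' protocols. The labels put the 9 samples into 3 groups of 3: healthy, early atretic and late atretic follicles. They number the samples of each group but do not say that a number marks a shared animal or day.

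The 3 tables used here each hold one of the authors' pairwise comparisons, with 21253 rows. Of these, 452 repeat another row exactly and were dropped, which left 20801 genes. Per the file headers, each table gives 2 columns of read counts, 1 per group; their values are not whole numbers, and the ratio of a group's values between 2 tables was nearly constant over genes, so they were read as group means of normalized counts, a signal scaled by the authors within each table. Over genes with a mean above 1000, that ratio had a median of 0.989 for early atretic, 1.03 for healthy and 1.05 for late atretic follicles, so each table was used only with itself, and means set side by side across tables carry this difference in scale. Per the file headers, the authors' log2 fold change compares the first group with the second, and it equalled the log2 ratio of both group means to within 0.01 at means above 50, so it was not shrunken. The deposited p-value and adjusted p-value are the authors' own, per the file headers; Benjamini-Hochberg adjustment of the deposited p-values over unique genes gave their adjusted p to within a relative difference of 7.7e-05. A p-value was present for 17386 genes in early atretic against healthy, 17366 in late atretic against healthy and 17552 in late against early atretic follicles, and 23, 76 and 61 further genes had a fold change without one. The test tool that gave these p-values, the counter, the gene annotation and its build are not given in the sources used here. Per the submitters' processing notes, Bowtie 0.12.2 and the mouse builds mm8 and mm9 were named with no role, although the samples are from buffalo.

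Values per sample were not used here, since the tables hold group means only, and 0 per-sample columns were left out. The depth of each library is therefore unknown, no standard deviation between samples could be computed, and no test across genes was run anew. For this case the design fixed beforehand the use of the authors' deposited calls at an adjusted p below 0.05. As a measure of error, the standard error implied by each deposited fold change and p-value was computed as the absolute log2 fold change divided by the z value of a two-sided normal test. This assumes such a test, which the sources do not state. The implied error was below the counting error of the group means in 0% of genes with both means above 1. Genes with a p-value close to 1 or none have no implied error.

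Gene names were taken from the gene identifiers, since some symbols in the tables had been turned into dates. Names were matched to a table of RefSeq genes of the assembly NDDB_SH_1, used for names only: 15413 of 16251 symbols and 3651 of 4550 LOC numbers were found in it. Members of the fixed lists that the tables hold under a LOC number, such as CYP19A1 as LOC102392019, were found this way. CYP11A1, HSD3B1 and CYP17A1 and several other list members had no match and were not analysed here. No coordinates are given because the build behind the tables is not given in the sources used here. Reads shared between paralogs, such as ribosomal protein genes and their pseudogenes, may have been split or lost by the authors' counting, so values of such families are uncertain.

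Before the data were examined, 23 gene lists and 11 lists of cell type markers, 34 in all, the tests of genes and lists, all alternatives but 1 and the rule for named genes were fixed; some tests of explanations in the closing section were chosen or given a condition later, as stated there. The rule took, per comparison, the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among genes with a symbol, an adjusted p below 0.05 and a mean of the higher group at or above the median of tested genes. It also took the 3 members of each list with the smallest adjusted p in early and in late atretic against healthy follicles, and landmark genes of granulosa cells whatever they showed. Lists were tested with Fisher's exact test, two-sided, for the share of members among higher and among lower genes against all other tested genes, with Benjamini-Hochberg adjustment over the 68 tests of a comparison. Members of a list are not independent of one another, which Fisher's exact test does not allow for. For each list, the count that passed with Benjamini-Hochberg adjustment over its own members is also given. The percentile of a list's median log2 fold change was taken among 10000 random lists of the same size, matched in 20 bins of mean expression, as a description of these data. Overlap between the comparisons that share healthy samples was set against 100 simulated draws of unchanged groups with the implied errors, over genes with a mean of at least 10 in the higher group.

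The list test and the adjustment were tested on simulated data with 200 genes changed by a log2 fold of 1 or 2 and errors drawn from each comparison, in 1 draw per comparison. In early atretic against healthy follicles (16832 genes simulated) 56% and 70.0% of the changed genes were recovered, in late atretic against healthy (16604 genes) 26% and 69%, and in late against early atretic (16723 genes) 29% and 67%. The share of false calls was 8.7%, 7.8% and 1.0% in the same order, at an adjusted p threshold of 0.05. The alternatives tried were an adjusted p threshold of 0.01, an added fold threshold, adjustment recomputed over all genes, genes at or above the median mean, fold changes recentred on the median of all genes and, chosen after the data were seen, genes with a p-value in all 3 tables. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.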

Results

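RNA was sequenced from granulosa cells, the somatic cells that line the ovarian follicle and make its estradiol and inhibin, of Chinese buffalo (Bubalus bubalis). The 9 samples came from follicles in 3 states, with 3 samples each from healthy, early atretic and late atretic follicles. Atresia is the degeneration that ends most follicles before they can ovulate, and death of granulosa cells is one of its marks. The authors' deposited tables hold 1 mean normalized read count per gene and group, with a log2 fold change, a p-value and an adjusted p for each of the 3 pairwise comparisons. Values per sample were not used here, so the depth of each library is unknown. Summed over 20801 genes, the group means of the authors' deposited tables came to between 13141820 and 14490733 normalized counts. Errors given as ± are standard errors implied by the deposited fold change and p-value under a two-sided normal test. For genes with a mean of at least 100, the median implied error on the log2 scale was 0.23 for early atretic against healthy, 0.29 for late atretic against healthy and 0.27 for late against early atretic. The labels do not say that the samples came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

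The comparison of early atretic with healthy follicles asks what differs in granulosa cells when atresia begins. Genes of granulosa function, steroid synthesis and cell division were lower in early atretic follicles, and genes of the extracellular matrix, matrix proteases and lysosomes and markers of macrophages were higher. INHA, which encodes the inhibin alpha subunit, fell by 2.03 ± 0.45 on the log2 scale in the authors' deposited table, to a mean of 78598 normalized counts in early atretic follicles. COL3A1, a fibrillar collagen, rose by 3.66 ± 0.36 on the log2 scale in the authors' deposited table, from 273 to 3446 normalized counts. Of 17386 tested genes in the authors' deposited table, 2251 passed the Benjamini-Hochberg adjusted p threshold of 0.05, of which 1494 were higher and 757 lower in early atretic follicles. A log2 fold change of at least 1 was also met by 1177 of the higher and 315 of the lower genes.

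Among genes with a symbol, an adjusted p below 0.05 and a mean at or above the median in the higher group, VAT1L had the largest rise, by 6.16 ± 1.19 on the log2 scale in the authors' deposited table, from 18.4 to 1316 normalized counts. MAP1LC3C, of the LC3 family of autophagosome proteins, rose by 5.17 ± 1.35, and THBS2, a secreted matrix glycoprotein, by 5.02 ± 1.22 in the authors' deposited table. The plasma membrane calcium pump gene ATP2B3 (4.94 ± 1.26), the actin cross-linker gene FLNC (4.54 ± 0.93), the cadherin gene CDH13 (4.51 ± 0.78) and the syndecan gene SDC1 (4.43 ± 1.21) followed in log2 fold change in the authors' deposited table. TINAGL1, CD109 and the macrophage scavenger receptor gene MSR1 rose by 4.33 ± 0.62, 4.25 ± 1.06 and 4.15 ± 1.21 in the authors' deposited table. Among the lower genes, ADCYAP1, which encodes the neuropeptide PACAP, fell by 3.06 ± 0.51 in the authors' deposited table, from 4119 to 493 normalized counts. SLC27A2, a fatty acyl-CoA synthetase gene, fell by 2.21 ± 0.32, HS3ST1 by 2.20 ± 0.42 and FBXO24 by 2.14 ± 0.47 on the log2 scale in the authors' deposited table. GRIN2D (-2.14 ± 0.41), the matrix proteoglycan gene ASPN (-2.11 ± 0.52), the mitochondrial carbonic anhydrase gene CA5B (-2.09 ± 0.40) and NDNF (-2.00 ± 0.40) had log2 fold changes of similar size in the authors' deposited table.

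Of 26 tested members of the granulosa list, 11 were lower and 2 higher in early atretic follicles, and 12 were lower and 3 higher when adjusted over the list alone. The share of lower members exceeded that of other genes (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 7.2e-08 over 68 list tests). FSHR, the receptor for follicle-stimulating hormone, fell by 1.16 ± 0.21, AMHR2, the receptor for anti-Müllerian hormone, by 1.27 ± 0.26, and the transcription factor gene FOXL2 by 1.07 ± 0.36 on the log2 scale in the authors' deposited table. FST, which encodes the activin-binding protein follistatin, fell by 2.00 ± 0.51 in the authors' deposited table, from 36036 to 9034 normalized counts. TNFRSF12A, the receptor for the cytokine TWEAK, rose by 2.05 ± 0.30 in the authors' deposited table. Of the steroid synthesis list, 5 of 15 tested members were lower, likewise 5 when adjusted over the list alone (Fisher's exact test, adjusted p = 0.0024), and none was higher, against 1 when adjusted over the list alone and 1 at an unadjusted p below 0.05. Of the list members found, 7 of the 17 steroid synthesis and 10 of the 26 granulosa ones are also in another list, FSHR and HSD17B1 in both, so these counts partly rest on the same genes. HSD17B1, which turns estrone into estradiol, fell by 2.02 ± 0.51 and FDXR, which passes electrons to mitochondrial steroid enzymes, by 1.46 ± 0.34 in the authors' deposited table. Several landmark genes had wide errors: LOC102392019, named CYP19A1 (aromatase) in the reference annotation, had means of 25077 in healthy and 5406 in early atretic follicles in the authors' deposited table, a log2 fold change of -2.21 ± 1.51 that did not pass. The luteinizing hormone receptor gene LHCGR (-2.41 ± 1.15), the inhibin beta A gene INHBA (-2.07 ± 1.00) and AMH (-0.26 ± 0.35) did not pass either in the authors' deposited table.

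Genes of mitosis made up the list with the highest share of lower members. Of 40 tested members, 19 were lower and none higher in early atretic follicles, against 34 lower and 1 higher at an unadjusted p below 0.05 and the same numbers, 34 and 1, when adjusted over the list alone (Fisher's exact test for lower, adjusted p = 4.2e-14). The list's median log2 fold change was -0.87, at percentile 0 among 10000 random lists matched on size and mean expression. CCND2, a cyclin of granulosa cell proliferation, fell by 1.68 ± 0.48, the phosphatase gene CDC25B by 1.55 ± 0.38, the mitotic transcription factor gene FOXM1 by 1.08 ± 0.28 and the checkpoint kinase gene BUB1 by 0.92 ± 0.26 in the authors' deposited table. Of 40 genes of DNA replication and repair in S phase, 0 passed in either direction by the authors' deposited adjusted p and 0 when adjusted over the list alone, against 5 lower at an unadjusted p below 0.05. Their median log2 fold change was -0.39, also at percentile 0 among matched random lists.

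Genes of the insulin-like growth factor system were higher in early atretic follicles, with 6 of 17 tested members higher and none lower (7 and 1 when adjusted over the list alone, Fisher's exact test for higher, adjusted p = 0.011). IGFBP5, a binding protein of insulin-like growth factors, rose by 3.48 ± 0.80 in the authors' deposited table, from 738 to 8228 normalized counts, and IGFBP3 rose by 2.13 ± 0.57. STC1, an inhibitor of the protease that cleaves such binding proteins, rose by 2.15 ± 0.49 and the insulin receptor substrate gene IRS2 by 2.10 ± 0.52 in the authors' deposited table. IGFBP2 had a log2 fold change of 0.53 ± 0.34 in the authors' deposited table and did not pass.

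Cell death genes moved in a few members. In the BCL2 family list, 4 of 18 tested members were higher, also 4 when adjusted over the list alone, and none was lower at any of these thresholds, with no excess by Fisher's exact test (adjusted p = 0.19). The pro-apoptotic genes BCL2L11 (BIM), BMF and BOK rose by 2.53 ± 0.35, 1.92 ± 0.33 and 1.96 ± 0.46 on the log2 scale in the authors' deposited table. BAX (0.09 ± 0.22) and BCL2 (0.88 ± 0.48) did not pass in the authors' deposited table. Of 26 tested death receptor and caspase genes, 2 were higher and 1 lower (2 and 0 when adjusted over the list alone). TNFRSF21, death receptor 6, rose by 2.26 ± 0.35, TNFRSF1B by 1.14 ± 0.29, and the caspase inhibitor gene XIAP fell by 0.48 ± 0.17 in the authors' deposited table, whereas FAS (-0.16 ± 0.28) did not pass. In the list of p53 targets and senescence genes, 5 of 22 members were higher and 2 lower (6 and 3 when adjusted over the list alone), among them GADD45A, a growth arrest gene, which rose by 2.55 ± 0.30 in the authors' deposited table, from 821 to 4792 normalized counts. PLK3 rose by 1.24 ± 0.27 in the authors' deposited table. Neither of these lists was enriched by Fisher's exact test (adjusted p = 1.00 for death receptors and 0.13 for p53 targets, higher).

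Of 29 tested lysosomal members, 12 were higher and none lower, at 13 and none when adjusted over the list alone and 16 and none at an unadjusted p below 0.05 (Fisher's exact test for higher, adjusted p = 2.3e-05). The cathepsin genes CTSH and CTSD rose by 3.01 ± 0.62 and 1.02 ± 0.17 in the authors' deposited table. Of 30 autophagy genes, 1 was higher, and 1 when adjusted over the list alone: TFEB, a transcription factor of lysosomal genes, rose by 1.12 ± 0.33 in the authors' deposited table. The antioxidant list had 5 of 31 members higher and 2 lower, with the same numbers when adjusted over the list alone (Fisher's exact test for higher, adjusted p = 0.40). SRXN1 and PRDX6 rose by 2.13 ± 0.36 and 1.17 ± 0.22, and GCLC, of glutathione synthesis, fell by 1.13 ± 0.20 in the authors' deposited table. ATF3 was the 1 of 25 unfolded protein response genes that was higher, also 1 when adjusted over the list alone, with a rise of 1.48 ± 0.25 in the authors' deposited table. This list's median log2 fold change was -0.34, at percentile 0.11 among matched random lists, and 7 members were lower at an unadjusted p below 0.05.

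Metabolic genes moved in both directions. Of 28 genes of cholesterol synthesis and uptake, 7 were lower and 3 higher (12 and 3 when adjusted over the list alone, Fisher's exact test for lower, adjusted p = 0.0013). FDFT1, squalene synthase, fell by 0.86 ± 0.31 and SOAT1, which esterifies cholesterol, by 0.69 ± 0.15 in the authors' deposited table. The 3 higher members all act in cholesterol export or transport, and they were APOE (1.59 ± 0.21), ABCA1 (3.14 ± 0.94) and ABCG1 (2.73 ± 0.54) as log2 fold changes in the authors' deposited table. Of 29 glycolysis and hypoxia genes, 7 were higher and 5 lower (10 and 5 when adjusted over the list alone, Fisher's exact test, adjusted p = 0.042 and 0.035). ENO2 rose by 2.96 ± 0.50 and the glucose transporter gene SLC2A1 by 0.79 ± 0.18, while HIF1A fell by 1.46 ± 0.29 in the authors' deposited table, from 47733 to 17393 normalized counts. None of 28 nuclear genes of oxidative phosphorylation and none of 48 cytosolic ribosomal protein genes passed, with 0 in either list when adjusted over the list alone. At an unadjusted p below 0.05 the first list had 1 lower and the second 3 higher members in the authors' deposited table.

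Of 32 tested matrix and collagen genes, 16 were higher and 3 lower (19 and 3 when adjusted over the list alone, Fisher's exact test for higher, adjusted p = 3.0e-08). COL6A2, of type VI collagen, rose by 1.93 ± 0.31, BGN, the proteoglycan biglycan, by 2.84 ± 0.48, and FN1, fibronectin, by 3.60 ± 0.81 in the authors' deposited table. Of 29 genes of matrix proteases and their inhibitors, 19 were higher and 1 lower (20 and 1 when adjusted over the list alone, Fisher's exact test for higher, adjusted p = 1.5e-12). MMP23B rose by 2.80 ± 0.30, ADAMTS2, which processes fibrillar procollagens, by 3.73 ± 0.48, and TIMP3, a metalloprotease inhibitor, by 1.33 ± 0.21 in the authors' deposited table. The 1 lower member was SERPINE2, a serine protease inhibitor, which fell by 1.20 ± 0.30 from 245253 to 106490.0 normalized counts in the authors' deposited table. In the list of TGF-beta, BMP and activin signalling, 10 of 39 members were higher and 6 lower (13 and 7 when adjusted over the list alone, Fisher's exact test, adjusted p = 0.0076 and 0.031). The receptor gene TGFBR2 (3.37 ± 0.48), the activin antagonist gene FSTL3 (1.97 ± 0.28) and SMAD9 (2.57 ± 0.43) were higher in the authors' deposited table, and INHA and FST were among the lower members.

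Markers of other cell types that could be present in the samples moved with these groups. Of 18 tested macrophage and monocyte markers, 11 were higher and none lower (15 and none when adjusted over the list alone, 15 and none at an unadjusted p below 0.05, Fisher's exact test for higher, adjusted p = 4.5e-07). CD68 rose by 2.93 ± 0.53, the receptor gene CSF1R by 3.19 ± 0.65 and the adaptor gene TYROBP by 4.39 ± 0.80 in the authors' deposited table. Of 14 tested stromal and fibroblast markers, 7 were higher (7 when adjusted over the list alone, Fisher's exact test, adjusted p = 0.00066), and 7 of the list's 15 members are also in another list, collagens among them. PDGFRB rose by 3.45 ± 0.54 and COL1A1 by 2.16 ± 0.37 in the authors' deposited table. Of 6 tested neutrophil markers, 4 were higher (4 when adjusted over the list alone, Fisher's exact test, adjusted p = 0.0044), with rises of 3.67 ± 0.88 for TREM1 and 1.33 ± 0.36 for LTF in the authors' deposited table. Endothelial markers were higher in 3 of 17 members (6 when adjusted over the list alone), among them ENG with a rise of 2.87 ± 0.66 in the authors' deposited table, and the list was not enriched among called genes (Fisher's exact test, adjusted p = 0.40). The median log2 fold change of the endothelial list was still 2.08, at percentile 99.98 among matched random lists. At an unadjusted p below 0.05, 8 endothelial markers were higher and 0 lower. Of 17 leukocyte, T and B cell markers 1 was higher, and 1 when adjusted over the list alone, namely CORO1A with a rise of 2.09 ± 0.57 in the authors' deposited table. Of 11 theca markers 1 was lower, and 1 when adjusted over the list alone, namely ALPL, which fell by 1.20 ± 0.30 in the authors' deposited table. Cytokine and chemokine genes had 8 of 23 members higher (11 when adjusted over the list alone, Fisher's exact test, adjusted p = 0.0030), and those with the smallest adjusted p were CXCL12 with a rise of 4.14 ± 0.64, LIF with 3.05 ± 0.58 and IL1R1 with 2.16 ± 0.46 in the authors' deposited table.

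Among genes at or above the median mean, 797 were higher and 700.0 lower, so the share of higher genes was 53.2% there against 66.4% of all calls. At an adjusted p threshold of 0.01 the lists of glycolysis genes in both directions and of cholesterol and TGF-beta genes among lower genes no longer passed Fisher's exact test, and among genes at or above the median mean the glycolysis list in both directions and the higher TGF-beta and cytokine lists did not.

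**Figure D1:**
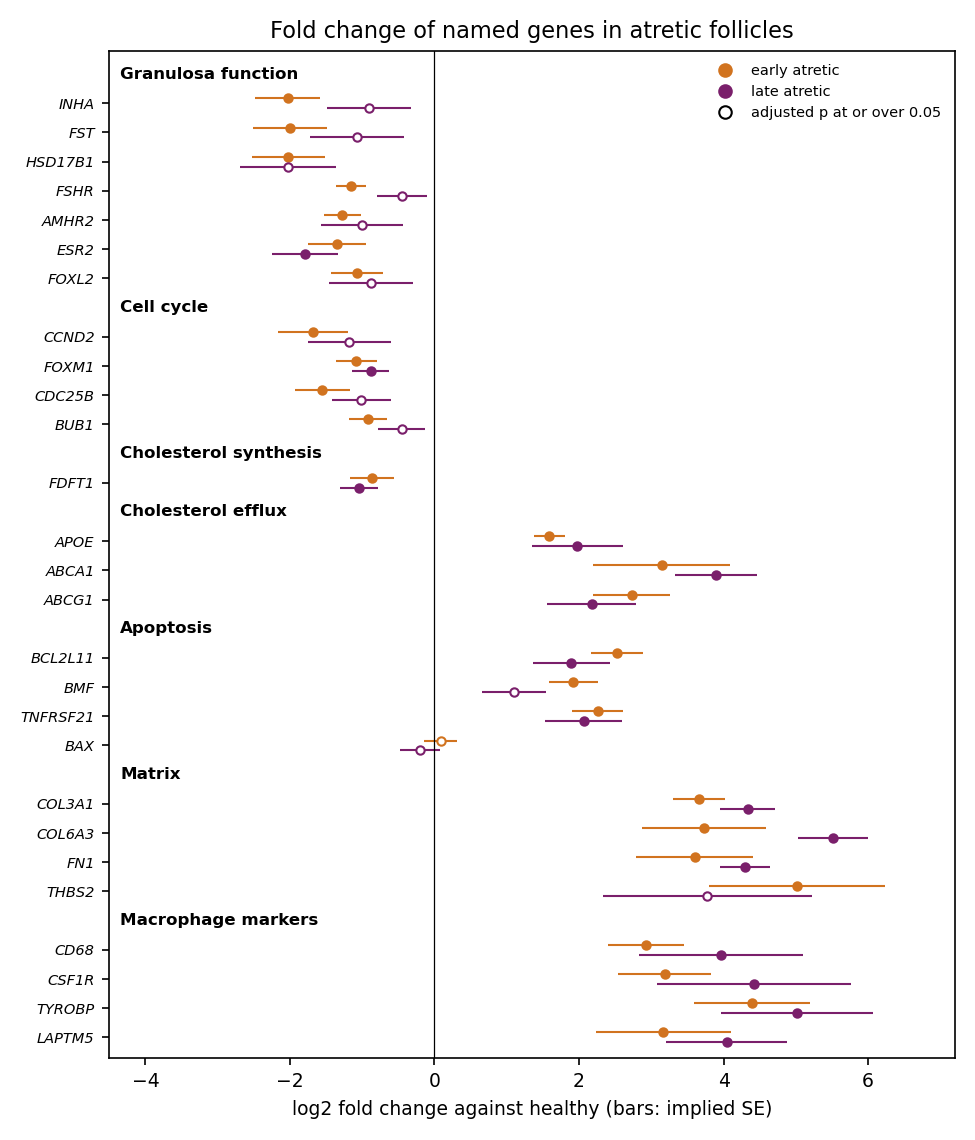
Log2 fold change against healthy follicles (x axis) of genes grouped by function (y axis), in early (orange) and late (purple) atretic follicles; bars are implied standard errors and filled points passed an adjusted p of 0.05 in the authors' deposited tables. INHA lies at -2.03 early and -0.91 late, and COL6A3 at 3.73 early and 5.52 late.

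The comparison of late atretic with healthy follicles asks what differs once atresia is advanced. Matrix genes, matrix proteases, lysosomal genes and macrophage markers were higher here too, and genes of cholesterol synthesis were lower. COL6A3, of type VI collagen, rose by 5.52 ± 0.48 in the authors' deposited table, from 176 to 8081 normalized counts, and FN1 rose by 4.29 ± 0.34. FDFT1 fell by 1.04 ± 0.26 in the authors' deposited table. Of 17366 tested genes in the authors' deposited table, 761 passed the Benjamini-Hochberg adjusted p threshold of 0.05, of which 692 were higher (90.9%) and 69 lower in late atretic follicles. A log2 fold change of at least 1 was also met by 663 of the higher and 47 of the lower genes.

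SFRP2, a secreted antagonist of WNT signalling, rose by 6.54 ± 0.62 in the authors' deposited table, from 5.75 to 517 normalized counts. VAT1L rose by 6.40 ± 0.42, and the cell adhesion genes CHL1 and L1CAM by 6.35 ± 0.72 and 5.98 ± 0.61 in the authors' deposited table. TREM2, a receptor of macrophages, rose by 5.52 ± 1.16, and TGFBI, a matrix protein gene induced by TGF-beta, by 5.51 ± 0.66 in the authors' deposited table. SDC1 (5.43 ± 0.76), ATP2B3 (5.41 ± 0.77) and FIBIN (5.40 ± 0.91) completed the 10 largest rises among genes with a symbol, an adjusted p below 0.05 and a mean at or above the median in the higher group in the authors' deposited table. The muscle creatine kinase gene CKM fell by 3.50 ± 0.63 from 216 to 19.0 normalized counts, and the potassium channel gene KCNG4 by 2.47 ± 0.53 in the authors' deposited table. SPOCD1 (-2.23 ± 0.70), MDGA1 (-2.19 ± 0.51), ANKRD44 (-2.06 ± 0.43) and the acyl-CoA synthetase gene ACSBG1 (-2.02 ± 0.41) followed as log2 fold changes in the authors' deposited table. WFDC1 fell by 1.96 ± 0.63, GALNT18 by 1.83 ± 0.29, ESR2, which encodes estrogen receptor beta, by 1.80 ± 0.46 and the sulfotransferase gene CHST8 by 1.70 ± 0.46 in the authors' deposited table.

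Of 34 matrix and collagen genes, 15 were higher (17 when adjusted over the list alone, Fisher's exact test, adjusted p = 5.4e-11) and none lower, against 1 lower at an unadjusted p below 0.05. COL3A1 rose by 4.34 ± 0.38 and COL1A1 by 3.12 ± 0.35 in the authors' deposited table. Of 29 protease and inhibitor genes, 12 were higher (13 when adjusted over the list alone, Fisher's exact test, adjusted p = 9.2e-09) and none lower at either p. ADAMTS2 rose by 4.15 ± 0.48, LOXL1, which crosslinks elastin, by 5.03 ± 0.66 and the gelatinase gene MMP2 by 3.41 ± 0.46 in the authors' deposited table. Lysosomal genes were higher in 8 of 29 members (11 when adjusted over the list alone, Fisher's exact test, adjusted p = 0.00017), with CTSH at 4.43 ± 0.78 and CTSK at 2.37 ± 0.53 as log2 fold changes in the authors' deposited table. In the TGF-beta list, 6 of 39 members were higher (10 when adjusted over the list alone, Fisher's exact test, adjusted p = 0.040), among them BMP6 (3.76 ± 0.65), TGFBR2 (3.31 ± 0.65) and SMAD9 (1.95 ± 0.45) in the authors' deposited table. This list no longer passed once fold changes were recentred on the median of all genes (adjusted p = 0.11 by Fisher's exact test) or among genes at or above the median mean (0.61).

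Macrophage markers were higher in 11 of 17 tested members (16 when adjusted over the list alone, Fisher's exact test, adjusted p = 1.3e-10). LAPTM5 rose by 4.05 ± 0.84, CD86 by 4.70 ± 1.06, TYROBP by 5.02 ± 1.05 and CD68 by 3.96 ± 1.14 in the authors' deposited table. The median log2 fold change of the macrophage list was 4.01, against -0.47 for the theca list, 0.91 for the stromal list and 1.04 for the endothelial list. It was 1.87 for the leukocyte, T and B cell list, 1.65 for the oocyte and cumulus list and 1.53 for the surface epithelium list. The neutrophil list had 0.85, the smooth muscle and pericyte list -0.14 and the erythroid list -0.69. Stromal markers were higher in 5 of 15 members (7 when adjusted over the list alone, Fisher's exact test, adjusted p = 0.0024), with COL1A2 at 3.00 ± 0.37 in the authors' deposited table. CD74, the invariant chain of MHC class II and 1 of only 2 members of that marker list in the tables, rose by 3.59 ± 0.79 in late and 2.77 ± 0.93 in early atretic follicles in the authors' deposited tables. Neutrophil markers were higher in 2 of 8 members (2 when adjusted over the list alone), S100A9 at 3.04 ± 0.96 and TREM1 at 3.72 ± 0.98 in the authors' deposited table, and endothelial markers in 1 of 17 (1 when adjusted over the list alone), ENG at 2.14 ± 0.54. CORO1A, at 2.31 ± 0.63, was the 1 of 17 leukocyte, T and B cell markers that passed in the authors' deposited table, and 1 did when adjusted over the list alone. Cytokine genes were higher in 3 of 23 members (7 when adjusted over the list alone), namely CXCL12 at 4.26 ± 0.57, LIF at 2.58 ± 0.69 and IL1RN at 3.16 ± 0.89 in the authors' deposited table.

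In the cholesterol list, 5 of 28 members were lower and 3 higher (12 and 3 when adjusted over the list alone, Fisher's exact test for lower, adjusted p = 1.3e-06). Among the lower ones were FDFT1 (-1.04 ± 0.26), with HMGCS1 (-1.35 ± 0.37), ACAT2 (-0.76 ± 0.24) and LOC102414371, named IDI1 in the reference annotation (-1.17 ± 0.38), which were chosen after their values in the authors' deposited table were seen. These 4 encode enzymes of sterol synthesis, and the 3 higher members were again ABCA1 (3.90 ± 0.57), APOE (1.98 ± 0.63) and ABCG1 (2.17 ± 0.61) in the authors' deposited table. In the glycolysis and hypoxia list, 2 of 29 members were higher, EGLN3 (1.88 ± 0.52) and NDRG1 (1.20 ± 0.35), and 2 lower, CA9 (-1.68 ± 0.51) and the phosphofructokinase gene PFKM (-1.34 ± 0.43, chosen after its value was seen), in the authors' deposited table (2 and 4 when adjusted over the list alone).

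Few genes of granulosa function and division passed in late atretic follicles. ESR2 was the 1 of 26 granulosa genes that was lower, against 7 at an unadjusted p below 0.05 and 3 when adjusted over the list alone, where 1 was also higher. None of 16 steroid synthesis genes passed by the authors' deposited adjusted p, against 4 lower and 1 higher at an unadjusted p below 0.05 and 1 of each when adjusted over the list alone. The log2 fold changes of HSD17B1 (-2.02 ± 0.67), INHA (-0.91 ± 0.58), FSHR (-0.44 ± 0.35) and LOC102392019, CYP19A1 in the reference annotation (-0.56 ± 1.47), did not pass in the authors' deposited table. FOXM1 was the 1 of 40 mitotic genes that was lower, with a fall of 0.88 ± 0.26 in the authors' deposited table, against 10 at an unadjusted p below 0.05 and 1 when adjusted over the list alone. POLD1, a subunit of DNA polymerase delta, was the 1 of 40 replication genes that was lower, and 1 was when adjusted over the list alone, with a fall of 0.77 ± 0.24 in the authors' deposited table. The medians of these 4 lists were -0.54 (granulosa), -0.47 (steroid synthesis), -0.52 (mitosis) and -0.36 (replication), at percentile 0, 0.01, 0 and 0 among matched random lists.

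IGFBP5, with a rise of 3.04 ± 0.67 in the authors' deposited table, was the 1 of 18 insulin-like growth factor genes that was higher, and 1 was when adjusted over the list alone. Among death genes, BCL2L11 rose by 1.90 ± 0.53, TNFRSF21 by 2.07 ± 0.53 and the initiator caspase gene CASP8 by 2.24 ± 0.59 in the authors' deposited table. These made up 1 of 18 BCL2 family and 2 of 26 death receptor and caspase genes, with the same numbers when adjusted over the list alone. BAX (-0.20 ± 0.28) did not pass in the authors' deposited table. None of the 30 autophagy, 31 antioxidant, 25 unfolded protein response, 28 oxidative phosphorylation and 48 ribosomal protein genes passed by the authors' deposited adjusted p, and 0 did in each when adjusted over the list alone. At an unadjusted p below 0.05 these lists held 1, 5, 1, 0 and 0 higher and 0, 1, 0, 0 and 4 lower members.

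Among genes at or above the median mean, 258 were higher and 46 lower. The implied errors were wider than in the early comparison, and on data simulated with these errors 26% of genes with a log2 fold change of 1 and 69% of those with 2 were recovered in the late comparison (200 of 16604 genes changed), against 56% and 70.0% in the early one (200 of 16832), with 7.8% and 8.7% of the calls false. Each share rests on 1 simulated draw. The 200 changed genes are fewer than the 761 late and 2251 early calls, so recovery in these data may differ.

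**Figure D2:**
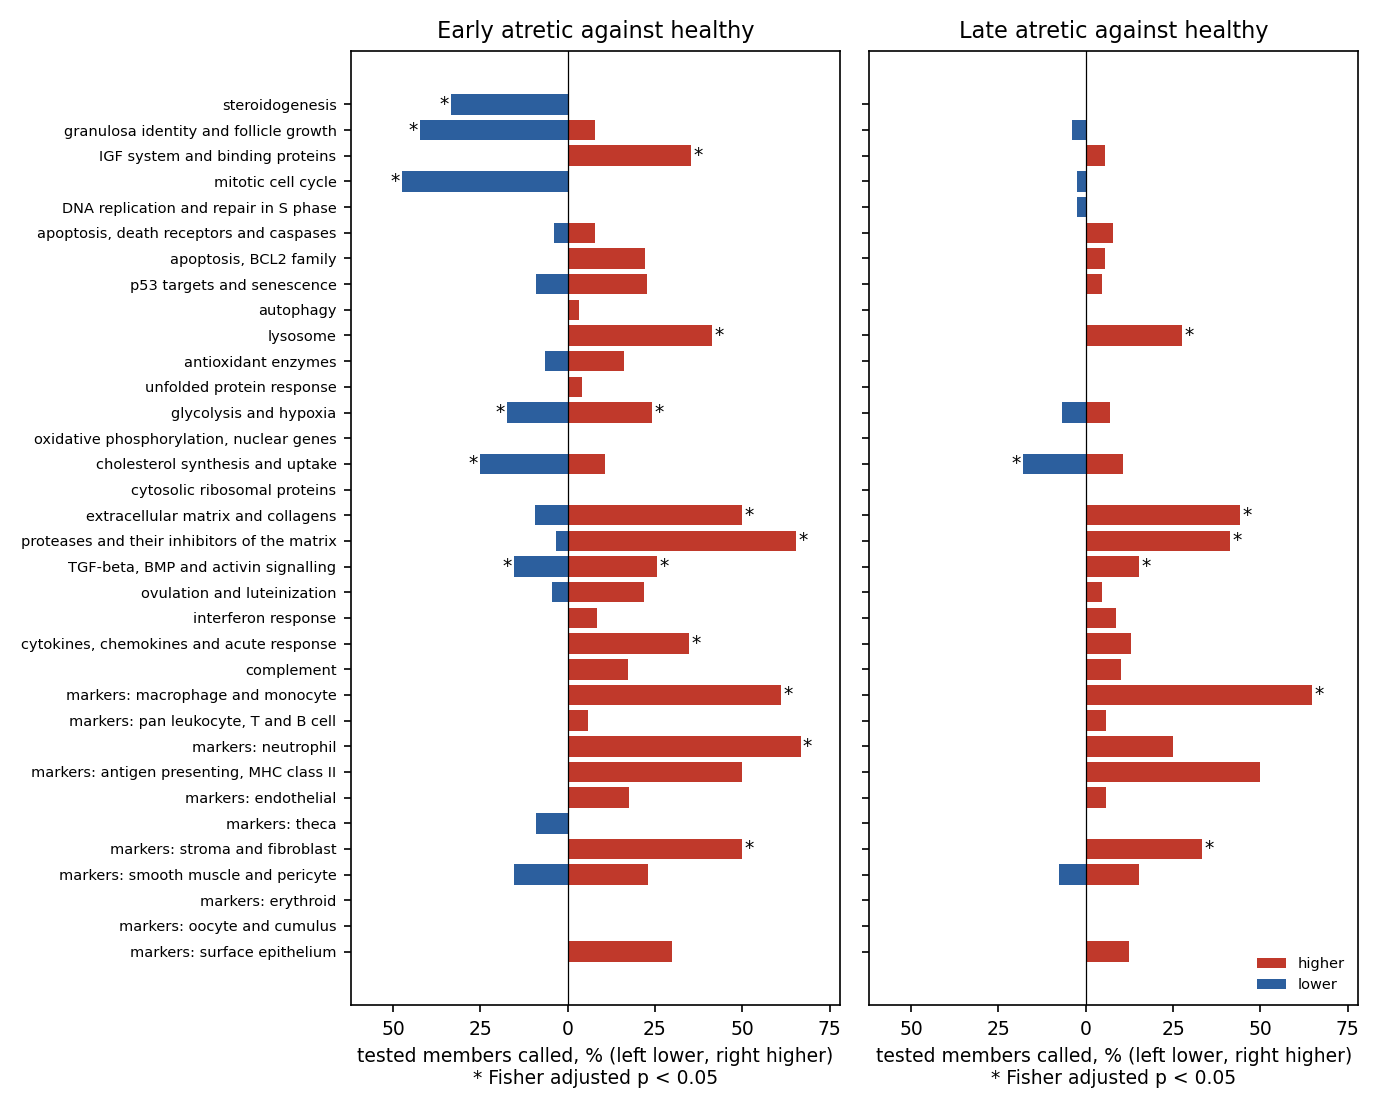
Share of each list's tested members (x axis, percent) that passed an adjusted p of 0.05 in the authors' deposited tables, drawn to the right for higher and to the left for lower, for early (left panel) and late (right panel) atretic against healthy follicles; stars mark Fisher's exact test adjusted p below 0.05. The mitosis list has 19 of 40 members lower in early and 1 of 40 in late atretic follicles.

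Both atretic stages were compared with the same healthy samples. Of 16947 genes tested in both, 1472 were higher in early and 689 in late atretic follicles, and 587 were higher in both, where independent lists would share 59.8. Lower in both were 39 genes, of 753 early and 69 late calls, where independent lists would share 3.07. None passed in opposite directions, against 4 at an unadjusted p below 0.05. Of the genes higher in early atretic follicles, 98.6% had the same sign in late ones, with a median log2 fold change of 1.81 early and 1.38 late in the authors' deposited tables. Of the genes lower in early atretic follicles, 95.9% had the same sign in late ones, with medians of -0.91 and -0.51 in the authors' deposited tables. These genes were picked by their early value, which by itself inflates the early fold change relative to the late one. The healthy samples shared by both comparisons also raise the share with the same sign by themselves. Across 11895 genes, which are not independent replicates, the fold changes of both comparisons had a Pearson correlation of 0.88 and a Spearman correlation of 0.76, where unchanged groups simulated against shared controls gave a Pearson correlation of 0.48. The covariance was 0.81 against 0.10 simulated, and 77.4% of genes had the same sign against 65.9% simulated. The healthy samples could not be split with group means alone, so part of the excess of shared calls over independent lists may come from the shared controls.

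**Figure D3:**
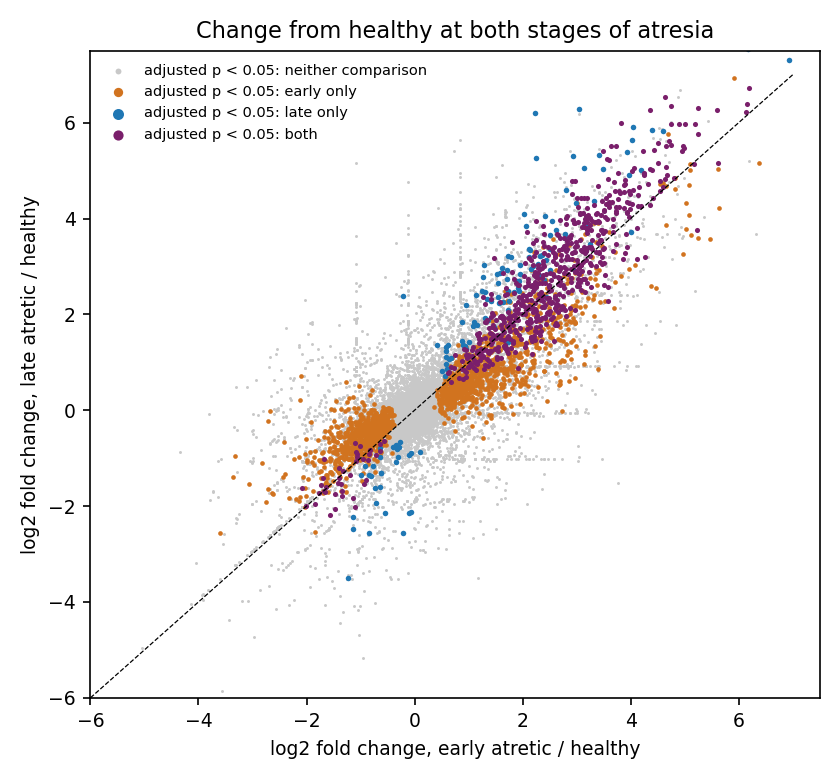
Log2 fold change in early (x axis) against late (y axis) atretic follicles, both relative to healthy, of 16946 genes in the authors' deposited tables (1 gene lies outside the axes); colors give the comparisons in which a gene passed an adjusted p of 0.05, and the dashed line marks equal values. The 587 genes higher in both stages lie in the upper right.

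The comparison of late with early atretic follicles asks what differs between both stages of atresia. Few genes passed between the stages: of 17552 tested in the authors' deposited table, 19 passed the Benjamini-Hochberg adjusted p threshold of 0.05, 3 higher and 16 lower in late atretic follicles. A further 61 genes had a fold change without a p-value and were not tested. In 1 draw simulated with these errors, 29% of genes with a log2 fold change of 1 and 67% of those with 2 were recovered (200 of 16723 changed). The small count therefore does not show that the stages are alike. With fold changes recentred on the median of all genes 31 passed, 2 higher and 29 lower. At an unadjusted p below 0.05 there were 941, 414 higher and 527 lower. Unchanged genes alone would pass that threshold at a share of 0.05, so the 941 do not count genes that differ between the stages. APOD, which encodes the lipid carrier apolipoprotein D, fell by 2.73 ± 0.57 in the authors' deposited table, from 502 to 75.8 normalized counts. RUNX2, a transcription factor gene, fell by 1.66 ± 0.39 from 4218 to 1339 normalized counts, and LTF, the iron-binding protein lactoferrin, by 1.55 ± 0.28 in the authors' deposited table. The chaperone gene CLGN rose by 1.16 ± 0.28, from 377 to 841 normalized counts, in the authors' deposited table.

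MFAP3L fell by 1.51 ± 0.33, the septin gene SEPT4 by 1.36 ± 0.31 and SYNPO2, an actin-binding protein gene, by 1.22 ± 0.22 in the authors' deposited table. BCL3, a regulator of NF-kappa-B, fell by 1.01 ± 0.24, PHGDH, the first enzyme of serine synthesis, by 0.96 ± 0.24, and SRF, a transcription factor of actin genes, by 0.80 ± 0.18 in the authors' deposited table. The ribosomal protein gene RPL37 fell by 0.85 ± 0.19 in the authors' deposited table. OXR1, an oxidation resistance gene, rose by 0.85 ± 0.19 and SH3D19 by 0.68 ± 0.16 in the authors' deposited table, and SH3D19 no longer passed with fold changes recentred on the median of all genes. The other 6 genes that passed have a LOC number only. Of the 19 genes, 18 had the opposite sign in early atretic against healthy follicles, and 8 of them had passed there. Early atretic samples enter both of these comparisons with opposite sign, which by itself gives opposite fold changes.

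No fixed list was enriched among these 19 genes (0 of 68 list tests by Fisher's exact test with Benjamini-Hochberg adjustment, 3 at an unadjusted p below 0.05). Of 48 cytosolic ribosomal protein genes, 1 was lower, RPL37, against 8 when adjusted over the list alone and 17 at an unadjusted p below 0.05, and none was higher. Their median log2 fold change was -0.31, at percentile 0 among matched random lists. RPS28 (-1.51 ± 0.40) and RPS18 (-0.64 ± 0.18) did not pass in the authors' deposited table. With fold changes recentred on the median of all genes, this list did pass among lower genes (Fisher's exact test, adjusted p = 0.0045). The mitosis list had a median of 0.35 and the macrophage list of 0.89, each higher than in all matched random lists, with 0 members passing in either by the authors' deposited adjusted p and 0 when adjusted over the list alone, against 1 and 0 higher at an unadjusted p below 0.05. The neutrophil list had a median of -1.24 and the endothelial list of -0.88, both at percentile 0, with LTF the 1 neutrophil marker that fell (1 when adjusted over the list alone) and no endothelial marker passing (1 lower at an unadjusted p below 0.05 and 1 when adjusted over the list alone).

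Over the order healthy, early and late, 0 genes passed in the same direction at both steps, against 24 higher and 5 lower at both at an unadjusted p below 0.05. At that unadjusted p 283 genes rose and then fell and 206 fell and then rose, where early atretic samples enter both steps with opposite sign. By the adjusted p there were 7 genes that rose and then fell and 1 that fell and then rose in the authors' deposited tables. The latter was CLGN, which had means of 659 in healthy and 373 in early atretic follicles. APOD, RUNX2, LTF, MFAP3L, SEPT4 and BCL3 rose and then fell, and the other gene of this kind has a LOC number only. In late atretic follicles the log2 fold change from healthy was -0.02 for APOD, -0.24 ± 0.42 for LTF and 1.16 ± 0.49 for RUNX2 in the authors' deposited table, and none of the 3 passed. A further 907 genes were higher and 718 lower in early atretic follicles alone, and 105 were higher and 30 lower in late ones alone. Such a count does not show that a gene differs between the stages. Only the 19 genes above passed the authors' test of that difference.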

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

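No test in this part was chosen after its result was seen; each gene stands here because the authors' own comparison of late with early atretic follicles tested the difference between the stages, and it passed their deposited Benjamini-Hochberg adjusted p of 0.05. No explanation was tested for single genes, and early atretic samples, which enter both steps with opposite sign, take part in each of these values.

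APOD had a log2 fold change of -2.73 between late and early atretic follicles in the authors' deposited table, after 2.73 ± 0.50 between early atretic and healthy ones. RUNX2 had -1.66 in late against early atretic follicles after 2.82 ± 0.48 at the first step in the authors' deposited tables. LTF had -1.55 after 1.33 ± 0.36, and MFAP3L had -1.51 after 1.41 ± 0.30, in the authors' deposited tables. SEPT4 had -1.36 after 1.06 ± 0.34, and BCL3 had -1.01 after 1.45 ± 0.29, in the authors' deposited tables. SYNPO2 had -1.22 in late against early atretic follicles, with a first step of 0.69 ± 1.08 that did not pass in the authors' deposited tables, so its error was several times wider there than the 0.22 at the second step.

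PHGDH had -0.96 and SRF -0.80 in late against early atretic follicles in the authors' deposited table, with first steps of 0.10 ± 0.23 and -0.11 ± 0.24 that did not pass. Both were also lower in late atretic than in healthy follicles, with log2 fold changes of -0.88 ± 0.28 and -0.93 ± 0.28 in the authors' deposited table. RPL37 had -0.85 in late against early atretic follicles in the authors' deposited table and passed in neither comparison with healthy follicles. CLGN had 1.16 after a first step of -0.82 ± 0.25, and OXR1 had 0.85 after -0.61 ± 0.22, which did not pass, in the authors' deposited tables. SH3D19 had 0.68 after -0.78 ± 0.37, which did not pass, in the authors' deposited tables; at the second step it no longer passed with fold changes recentred on the median of all genes.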

How the results depend on the processing

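The setting limited to genes with a p-value in all 3 tables was chosen only after the data were seen. No paired analysis was possible because the columns hold 1 mean per group and carry no sample numbers. For the same reason leaving out samples, other splits of the samples, other normalizations, pseudocounts, set tests with an estimated correlation and limma or count models could not be run, and the depth of single libraries limits the results in an unknown way. No named gene that had passed changed direction under the alternatives followed for single genes. Changes of sign among genes that had not passed were not counted. Adjustment recomputed over all genes and the limit to genes with a p-value in all 3 tables kept each count of genes within 1.5 times of its value.

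At an adjusted p of 0.01, early atretic against healthy follicles gave 1392 genes in place of 2251, of which 348 were lower. Late atretic against healthy gave 447 in place of 761, with 426 higher and 21 lower. Late against early atretic gave 4 in place of 19, with 0 higher and 4 lower. At this threshold 2 genes rose and then fell and 0 fell and then rose, 339 were higher and 7 lower in both stages. With a log2 fold change of at least 1 added, early atretic against healthy gave 1492 genes with 315 lower, late against early atretic gave 1 higher, 24 genes were lower in both stages and 0 fell and then rose. These counts are lower because the thresholds are stricter.

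Among genes at or above the median mean, early atretic against healthy gave 1497 genes with 797 higher, late atretic against healthy gave 304 with 258 higher, late against early atretic gave 5 higher, and 242 genes were higher in both stages. Fewer genes are tested in this setting. With fold changes recentred on the median of all genes, which lay at 0.02, 0.03 and 0.06 on the log2 scale in the 3 comparisons, late against early atretic gave 31 genes with 29 lower, and 1 list passed, the ribosomal proteins. The share of higher genes moved from 66.4% to 63.8% in early and from 90.9% to 89.1% in late atretic against healthy follicles under recentring. Of the list results followed over the alternatives, 4 no longer passed at an adjusted p of 0.01, 5 among genes at or above the median mean and 1 with recentring, while the surface epithelium list passed among higher genes in early atretic follicles at or above the median mean (Fisher's exact test, adjusted p = 0.018); the cause was not tested.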

Other observations

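The tests of expression nearer to healthy at the late stage, of a lower share of granulosa RNA (with its restriction to less abundant markers) and of stromal RNA in late atretic follicles were chosen after the results they bear on were seen, and in the tests of wider errors, of macrophage RNA and of stromal RNA in early atretic follicles 1 condition each was added after the values had been seen (a margin of 1.96 square roots of the count, a power of at least 80%, and counting a marker without an error as undecided), each of which moved its outcome to undecided.

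Genes tied to ovulation and luteinization, 23 of them tested, had 5 higher members and 1 lower in early atretic follicles (6 and 3 when adjusted over the list alone, Fisher's exact test for higher, adjusted p = 0.15). ADAMTS1, a protease gene induced before ovulation, rose by 2.64 ± 0.50, RUNX2 by 2.82 ± 0.48 and RUNX1 by 0.80 ± 0.19 in the authors' deposited table. In late atretic follicles ADAMTS1 was the 1 of 22 that passed, with a rise of 2.21 ± 0.57 in the authors' deposited table, and 1 did when adjusted over the list alone. PTGS2 had 0.93 ± 0.59 early and 0.08 ± 0.64 late and did not pass in the authors' deposited tables. Complement genes were higher in 4 of 23 members early and 2 of 20 late (5 and 3 when adjusted over the list alone). CLU, clusterin, rose by 1.52 ± 0.34 early, and the complement receptor gene C5AR1 by 3.58 ± 0.84 early and 4.82 ± 1.01 late in the authors' deposited tables. Interferon response genes were higher in 2 of 24 members early and 2 of 23 late (2 and 4 when adjusted over the list alone), in each case with PSMB8 among them, at 1.15 ± 0.25 and 0.96 ± 0.30 in the authors' deposited tables.

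Epithelial keratins rose early: KRT8 by 2.58 ± 0.47, from 1807 to 10809 normalized counts, and KRT18 by 2.87 ± 0.45 in the authors' deposited table, with CDH1, E-cadherin, at 2.95 ± 0.51. They made up 3 of 10 tested surface epithelium markers (4 when adjusted over the list alone), and in late atretic follicles CDH1 alone of 8 passed, at 3.02 ± 0.83 in the authors' deposited table (1 when adjusted over the list alone). Smooth muscle and pericyte markers parted. TAGLN rose by 2.02 ± 0.28 and CNN1 by 3.26 ± 0.59 while MCAM fell by 1.90 ± 0.48 in early atretic follicles in the authors' deposited table, with 3 of 13 higher and 2 lower in all (3 and 4 when adjusted over the list alone). In late atretic follicles 2 of 13 were higher, TAGLN at 2.80 ± 0.37 and CNN1 at 3.86 ± 0.58, and 1 lower, ACTG2 at -1.34 ± 0.38, in the authors' deposited table, with the same numbers when adjusted over the list alone. No erythroid marker (6 tested) and no oocyte or cumulus marker (12 tested early, 13 late) passed by the authors' deposited adjusted p, with 0 at an unadjusted p below 0.05 and 0 when adjusted over the list alone. The most abundant of these in late atretic follicles were HBA1 at 10.3 and SYCP3 at 32.2 normalized counts in the authors' deposited table.

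Some genes with large differences between group means have no p-value in the tables, so they were not tested. Only group means are given, so such a difference may come from part of a group's samples rather than from all of them. The means below therefore do not show a difference between the stages. STAR, which brings cholesterol into mitochondria, had means of 57.9 in healthy and 717 in early atretic follicles in the authors' deposited table, and its late log2 fold change of 4.51 ± 1.51 did not pass. The neutrophil and monocyte genes S100A8 and S100A9 went from 12.6 to 201 and from 19.7 to 349 in early atretic follicles in the authors' deposited table. TNFAIP6, a gene of cumulus matrix, had means of 5.74 in healthy and 272 in late atretic follicles in the authors' deposited table, and SIGLEC1, a macrophage lectin gene chosen after its values were seen, had 12.4 and 569.

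Fewer genes were lower in late than in early atretic follicles, 69 against 757. With the early fold changes tested at the implied errors of the late comparison, 213 genes were lower, against 774 with their own errors, so wider errors may account for part of the gap. The 213 lies just above 207, 3 times the late count and the bound set beforehand for excluding wider errors as the cause, but by less than the margin added later. The late fold changes tested at the early errors gave 344. At either set of errors the early fold changes thus gave more lower genes, 213 against 69 at the late errors and 774 against 344 at the early ones. A gap therefore stayed with the errors held alike, though the spread of these counts between samples is unknown. The other candidate explanation is expression nearer to healthy at the late stage: the 168 members of the 6 lists enriched among early lower genes had a median late against early log2 fold change of 0.096, at percentile 97.4 of matched random lists, whose upper bound (two-sided 95% range) was 0.0967. Taken singly, the mitosis list lay above all matched random lists and the steroid synthesis and granulosa lists at percentile 99.49 and 98.94, against 75.3 for TGF-beta, 18.7 for cholesterol and 15.9 for glycolysis genes, so the pooled median runs over lists that part. Early atretic samples also enter both the choice of these lists and their values, so how much wider errors and a return toward healthy each add cannot be told. A difference between the follicles collected for both stages stays open too, as untested.

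Macrophage markers were higher in both atretic stages, where CD68, the most abundant of them late, had means of 121, 919.9 and 1833 in healthy, early and late atretic follicles in the authors' deposited tables. A lower share of granulosa RNA would raise alike the markers of every other cell type that granulosa cells do not express. In late atretic follicles the macrophage median exceeded the theca median by 4.46 (95% bootstrap interval 3.22 to 5.14). Over the 7 theca markers no more abundant in healthy follicles than the top macrophage marker, the gap was 4.02 (2.87 to 5.02). These late values argue against a like rise of macrophage and theca markers. The 5 late surface epithelium markers within the same limit of abundance had a median of 3.02, below the macrophage one by 0.97 (-0.39 to 3.95). In early atretic follicles the gap to theca was 2.69 (1.13 to 3.22), and 1.95 (0.58 to 2.91) within that limit. The early medians of the surface epithelium (2.72), neutrophil (2.27) and endothelial markers (2.08) lay near the macrophage median of 2.87, so the early values do not decide. These intervals resample the markers of a list, so they measure the spread between markers and not between samples. The theca list lacks CYP17A1, which had no match. RNA of macrophages in the samples is a candidate source, and it would keep the markers in one ratio between the stages. Across 17 markers, the late against early log2 fold changes ran from 0.515 to 4.91 and spread no more than their errors (Cochran's Q of 3.31 with a chi-square p of 1.00, against 0.029 over 564 genes higher in both stages). This met the outcome set beforehand for macrophage RNA, but the test would find a spread of 1 log2 unit in only 48.9% of simulated cases. Both the chi-square p and the simulation take the errors of the markers as independent, although all come from the same samples. Shared errors would narrow the spread, so this outcome does not count for macrophage RNA. Macrophage RNA and expression by the granulosa cells themselves cannot be told apart. Of the 18 markers, 13 had a mean of at least 10 in healthy follicles and 3 are also in another list.

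Matrix genes were higher in both atretic stages, and RNA of stromal or theca cells is a candidate source. Taken whole, the theca list did not rise with them: its median log2 fold change was 0.18 early and -0.47 late. For the 7 theca markers no more abundant in healthy follicles than the top macrophage marker, the median was 0.92 early and -0.03 late. The whole list therefore does not exclude theca RNA in early atretic follicles. Of the 11 tested theca markers 0 passed as higher at either stage, against 3 early and 0 late at an unadjusted p below 0.05. Stromal RNA would bring other stromal transcripts up as far as the collagens if healthy granulosa cells expressed neither. LUM, PDGFRA and DCN had means of 1158, 361 and 270 in healthy follicles, so a smaller rise need not speak against stromal RNA. For COL1A1, COL1A2 and COL3A1 the median log2 fold change was 2.69 in early atretic follicles. Of 5 other stromal markers, DCN (2.12 ± 0.60), LUM (1.65 ± 0.90), PDGFRA (2.40 ± 0.46), OGN and DPT (0.46 ± 0.88) in the authors' deposited table, 1 had an upper 95% bound below that median, namely DPT, which met the outcome set beforehand for stromal RNA (at most 1), but OGN has no error and could be a second. In late atretic follicles DCN (1.63 ± 0.71), LUM (1.89 ± 0.70), PDGFRA (2.16 ± 0.64), OGN (-0.73 ± 0.64) and DPT (0.59 ± 0.75) all lay below the collagen median of 3.12 in the authors' deposited table, and the upper 95% bounds of 3 did, but once the error of the collagen is counted only 2 of 5 lay below it, OGN and DPT, the least abundant of them. PDGFRB, a stromal marker outside these 5, lay above the collagen medians, at 3.45 ± 0.54 early and 3.76 ± 0.65 late in the authors' deposited tables. The 15 stromal markers, collagens included, had a median of 1.67 early and 0.91 late. Among them, the 8 no more abundant in healthy follicles than the top macrophage marker had medians of 1.13 and 0.03. These list medians lie below those of the collagens. The errors of DCN, LUM and PDGFRA are too wide to decide, so stromal RNA and matrix synthesis by granulosa cells cannot be told apart.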
